A study of Mus musculus with 2 samples.

How the data were processed

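Whole uterus from a Mettl14 f/f and a Mettl14 d/d mouse sample on gestational day 4 was digested enzymatically at 37 °C over no more than 30 min, strained through 40 µm, cleared of red cells and loaded on a droplet system for 3′ tag counting, per the labels' protocols. The stated target was 8000 to 10000 cells per library. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization, per the file headers. Cell Ranger 3.0.1 and the mm10 genome are named per the submitters' processing notes, while the matrix headers name cellranger 6.0.1, so the version used is open. The lowest barcode total was 500 UMIs in both matrices, so barcodes below that had been left out before deposit. Each matrix listed 31053 genes. Where identifiers shared a symbol, it went to the identifier with the highest total, and the other 36 identifiers were kept apart.

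Cells were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs, which left 7610 f/f and 6325 d/d barcodes. Doublets were scored per library with Scrublet in scanpy 1.11.5. The highest-scoring barcodes at 0.8% per 1000 barcodes were marked, 533 in f/f and 355 in d/d, which removed 515 and 348 of the barcodes that had passed. The automatic threshold marked 0 f/f barcodes and so did not work there, and 400 d/d barcodes (6.01%). Counts per cell were scaled to 10000, logged, reduced to 2000 variable genes and 30 principal components, and clustered without integration by Leiden on a graph of 15 neighbours at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Clusters were named from marker genes chosen before the data were examined, as were the filters, the gene lists, the rule for named genes and the first set of alternative settings. The scoring rule that assigns a cluster to a class was set afterwards. A cluster stayed unnamed with fewer than 3 detected markers, with a mean marker log2 fold under 1 over the median cluster, with more markers of another class than of its own among its 10 leading genes, or with few UMIs and no own marker among them. Epithelial cells were clustered again at resolution 0.5, and a sub-cluster led by endothelial genes was set aside as unnamed.

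UMIs were summed per library and class and divided by the class total to give CPM. Classes with at least 100 cells in both libraries were compared, which gave stroma, epithelium, smooth muscle, pericyte, blood endothelium and macrophage or monocyte. Cells are not replicates, so no test was made across samples. Shares carry exact Clopper-Pearson intervals, sums exact Poisson intervals and ratios conditional exact intervals, all at 95%. A count of 0 was set to 3 counts over the class to give a bound, which leaves out counting error in the other library. For gene lists, members with at least 20 UMIs in the class were used and at least 5 were needed. A member counted as higher or lower at 1.5-fold with at least 50 UMIs in the higher library. The list median is given with its percentile among 10000 random lists of the same size matched on mean expression, a description of these libraries, and with an interval from 1000 redraws of the counts. Of 28 lists, that of stratified epithelium had too few measured genes in each class. The genes named in the text are Mettl14, 14 key genes of uterine biology, and per class the 12 with the highest and the 12 with the lowest folds in stroma, epithelium and smooth muscle, or 4 and 4 elsewhere, ranked by the interval bound nearest 0. They needed 50 UMIs and 20 CPM in the higher library and at least 10% of the CPM of their highest class there, since free RNA could supply the rest. Stromal markers exceeded this limit in f/f smooth muscle (29.7% of their stromal level), pericytes (61.9%) and macrophages (39.7%). In these classes the limit may not remove every gene that free RNA could supply. Up to 4 members of each list were added by the same ranking, and not every gene that the rule allows is named.

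The median log2 fold over all genes with at least 100 UMIs was -0.14 in stroma, -0.13 in epithelium, -0.13 in smooth muscle, -0.19 in pericytes, -0.04 in blood endothelium and -0.09 in macrophages. Scaling by the trimmed mean of M values (TMM, edgeR 4.0.16) moved it to 0.06 in epithelium, 0.05 in smooth muscle, 0.05 in pericytes and 0.39 in macrophages. Totals without mitochondrial and ribosomal protein genes moved it to 0.06 in epithelium and -0.19 in macrophages. Folds should be read relative to these shifts. Intervals and the list percentile were tested on simulated data in which 200 genes were changed. The simulated counts were independent Poisson draws, the model that the intervals assume. Extra spread between cells and genes that move together were therefore not covered. In stroma (10642 genes) the intervals held the true value for 96.0% of 2-fold and 94.0% of 4-fold changes and for 95.6% of unchanged genes, in epithelium (5475 genes) for 99.0%, 93.0% and 94.9%, and in blood endothelium (8261 genes) for 96.0%, 95.0% and 95.5%. Among 100 unchanged lists 7, 2 and 6 fell outside the central 95%. Alternatives covered the mitochondrial and UMI filters, doublets, clustering, scaling, equal weight per cell, the list minimum and the list statistic. Added after seeing the data were the clusters shared by both libraries, each f/f epithelial part as reference, and the endothelial-led sub-cluster kept. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3.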

Results

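Single-cell RNA sequencing was performed on whole mouse uterus collected on gestational day 4, the day on which the uterus becomes receptive to the embryo. The labels name 1 Mettl14 f/f sample, a notation for alleles flanked by recombination sites, and 1 Mettl14 d/d sample, a notation for deleted alleles. Mettl14 encodes a subunit of the methyltransferase complex that places N6-methyladenosine on RNA. The f/f library held 8164 barcodes and 55080123 unique molecular identifiers (UMIs), and the d/d library held 6661 barcodes and 44745031 UMIs. After filtering, 7095 f/f and 5977 d/d cells remained, with a median of 6085 and 5217 UMIs and of 2301 and 1981 genes per cell. With 1 library per genotype no difference has a replicate check, so no p-value is given. All 95% intervals cover counting error only, and values compare these libraries, not the genotypes at large. Many genes are given by their log2 fold alone. Folds are d/d over f/f throughout, and log2 folds rest on UMIs scaled to the class total (CPM). Cell classes were rebuilt here from marker genes and may differ from those of the study.

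Mettl14 RNA was lower in the d/d library. Over all kept cells Mettl14 stood at 15.5 CPM in f/f (753 UMIs, interval 14.4 to 16.6) and 5.53 CPM in d/d (223 UMIs, interval 4.83 to 6.31), a ratio of 0.358 (0.307 to 0.416). The gene (ENSMUSG00000028114) lies on the minus strand of chromosome 3 at 123368297 to 123386108 in the GRCm38 annotation. Stroma-like cells had 14.6 CPM in f/f and 2.38 CPM in d/d, a ratio of 0.163 (0.109 to 0.234). Smooth muscle-like cells had a ratio of 0.133 (0.075 to 0.232), epithelium-like cells 0.243 (0.139 to 0.416) and pericyte-like cells 0.360 (0.195 to 0.661). Blood endothelium-like cells had 18.8 CPM in f/f and 18.3 CPM in d/d, a ratio of 0.974 (0.715 to 1.33). In macrophage- or monocyte-like cells the ratio was 0.430 and in natural killer (NK) or innate lymphoid-like cells 1.41, with intervals of 0.164 to 1.12 and 0.475 to 3.51 that hold 1. The labels name neither the deleted exons nor the Cre driver, and a 3′ tag can lie outside a deleted part, so a remaining tag does not show an intact transcript. Mettl3, which encodes the catalytic partner of METTL14, stood at 18.8 CPM in f/f stroma and 8.21 CPM in d/d stroma. Its log2 fold was -1.20 in stroma (-1.51 to -0.90) and -0.57 in the stromal cluster that both libraries shared, -0.11 in epithelium and -0.34 in blood endothelium. The 18 measured genes of the m6A machinery, the writers, erasers and readers of this mark, had a median log2 fold of 0.07 in stroma, at percentile 90.2 of random lists, and their summed UMIs gave -0.02. Among them Rbm15 (0.84) and Wtap (0.81), adaptors of the writer complex, were higher in d/d stroma.

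**Figure D1:**
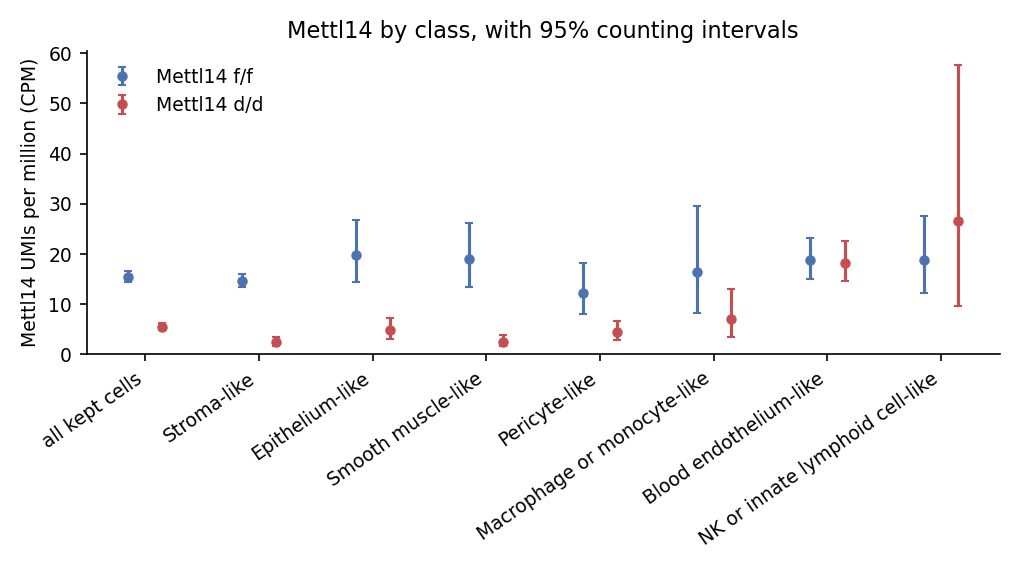
Mettl14 CPM in all kept cells and in 7 cell classes of the f/f and d/d libraries, with exact 95% Poisson intervals for counting error. The d/d value lies below the f/f value in stroma-like (2.38 against 14.6), smooth muscle-like, epithelium-like and pericyte-like cells and close to it in blood endothelium-like cells (18.3 against 18.8).

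In percentage points the cell makeup of the libraries differed most in stroma, smooth muscle and pericytes. Stroma-like cells made up 65.6% of kept f/f cells (64.5 to 66.7) and 28.4% of d/d cells (27.3 to 29.6), a ratio of 0.434 (0.410 to 0.458). Smooth muscle-like cells made up 6.29% of f/f and 24.7% of d/d cells (ratio 3.93, 3.54 to 4.38). Pericyte-like cells made up 5.31% and 20.1% (ratio 3.78, 3.36 to 4.25), with a ratio of 2.31 when each library was clustered separately. Of these cells, 66 in f/f and 586 in d/d lay in cluster 8. Its mean marker log2 fold was 4.10 for pericytes and 3.11 for smooth muscle, so its class is less certain. The epithelium-like share was 2.49% (177 cells) and 2.61% (156 cells), with a ratio of 1.05 (0.838 to 1.30), but 0.721 with a sub-cluster kept that was led by endothelial genes and left out after the data were seen. Blood endothelium-like cells made up 6.91% and 10.1% (ratio 1.46, 1.30 to 1.65). Their ratio was 1.26 with doublets kept and 1.19 with the automatic doublet threshold. The sub-cluster led by endothelial genes, with 88 f/f and 5 d/d cells, is not counted among them. Macrophage- or monocyte-like cells made up 3.21% and 4.95% (ratio 1.54, 1.29 to 1.84, and 2.45 with a minimum of 2000 UMIs). NK or innate lymphoid-like cells, which populate the decidua in early pregnancy, made up 3.30% of f/f and 0.586% of d/d cells (ratio 0.178, 0.121 to 0.254), but the ratio was 0.688 with separate clustering. T cell-like cells made up 0.719% and 4.32% (ratio 6.01, 4.43 to 8.28), with ratios of 30.8 at a minimum of 2000 UMIs and 3.15 with separate clustering. Mesothelium-like cells, from the outer lining of the uterus, numbered 36 in f/f and 0 of 5977 in d/d, which allows a share of up to 0.0502% (3 cells) or, by the exact interval, 0.0617%. Unnamed clusters held 3.61% of f/f and 1.99% of d/d cells. Shares depend on how cells were released from the tissue by enzymes and on the minimum of 1000 UMIs.

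**Figure D2:**
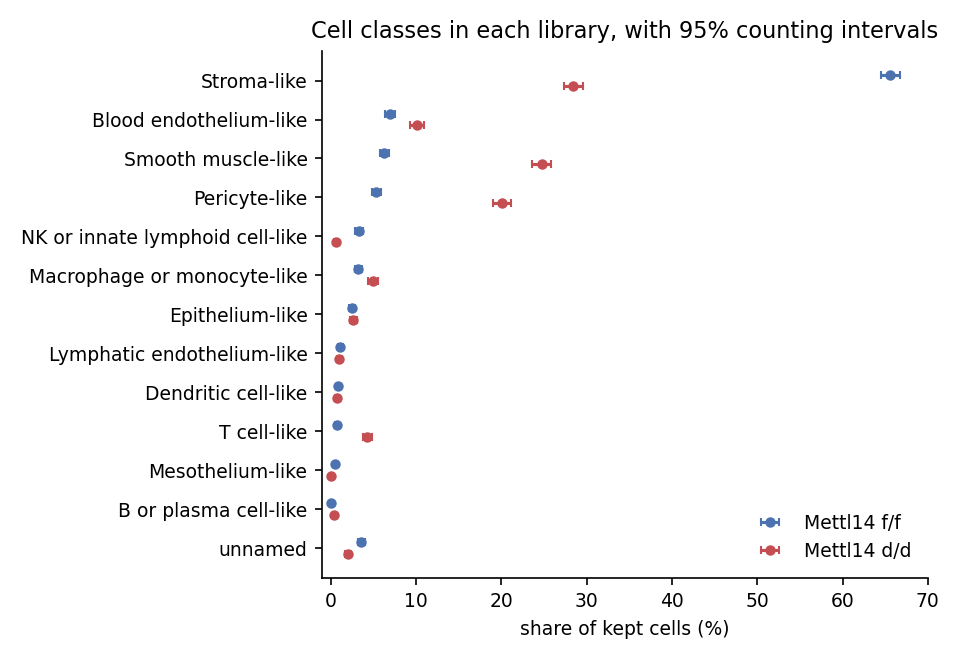
Share of kept cells in each class, in percent, for the f/f and d/d libraries with exact 95% binomial intervals for counting error. Stroma-like cells stand at 65.6% in f/f and 28.4% in d/d, smooth muscle-like cells at 6.29% and 24.7%, and epithelium-like cells at 2.49% and 2.61%.

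Stroma-like cells, the fibroblasts that form the decidua after implantation, had higher levels of immediate early, inflammatory and p53 response genes and lower levels of proliferation genes in the d/d library. Cdkn1a, the cell cycle inhibitor p21, had 540 UMIs in f/f and 3384 in d/d stroma (log2 fold 4.02, 3.89 to 4.15). Mki67, a marker of cycling cells, stood at 47.6 and 21.2 CPM (log2 fold -1.17, -1.36 to -0.98). Of 24 measured proliferation genes, 13 were at least 1.5-fold lower and 1 higher in d/d, and their median log2 fold of -0.63 (-0.70 to -0.51) lay below all 10000 random lists matched on mean expression. Examples were Cenpf (3.99-fold lower), Ube2c (log2 fold -1.30), Ccna2 (-1.28) and Tpx2 (-1.23), which act in mitosis. The stroma of the libraries sat in different clusters: clusters 0, 1 and 9 held 37.9%, 33.4% and 12.1% of f/f stroma, cluster 4 held 59.7% of d/d stroma, and cluster 3 held 8.85% of f/f and 36.4% of d/d stroma. Cluster 11, led by mitotic genes, held 7.35% of f/f and 3.59% of d/d stroma. A cluster almost wholly of 1 library may reflect that library, so for some gene lists and genes values within the shared cluster 3 are given too. Cluster 3 was led by Clec3b, Adh1, Inmt and Abca8a. Its median was 4197 UMIs, against 6971 in cluster 0 and 9337 in cluster 4. Values within it describe this part of the stroma and need not hold for the rest. In cluster 3 the proliferation median was -1.10 (-1.41 to -0.71), with 2 of 16 measured genes higher and 2 lower, and -0.15 when UMIs were summed.

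Immediate early and heat shock genes, which also respond to enzymatic dissociation, were higher in 17 of 18 cases in d/d stroma, with a median log2 fold of 2.11 (2.09 to 2.14) and 1.07 in the shared cluster. Fos (2.44), Nr4a1 (2.64), Ier3 (3.40) and Hspa1a (2.57) were among them. Of 15 inflammatory mediators 10 were higher, with a median of 1.77 and 1.51 in the shared cluster. Cxcl1, a neutrophil attractant, had a log2 fold of 4.15 (2.34 in the shared cluster), Nfkbia 2.32, Icam1 1.77 and Cxcl14 1.55, the last with -0.43 in the shared cluster. Genes of the p53 response had a median of 1.05 and 1.09 in the shared cluster, with 12 of 17 higher, among them Gadd45a (5.67-fold), Phlda3 (log2 fold 1.36) and Sesn2 (1.26). Interferon response genes had a median of 0.63 and 0.38 in the shared cluster, with Isg15 at 2.35, Rtp4 at 2.08 and Irgm1 at 1.27.

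Hormone receptor genes differed little in stroma. Esr1, the estrogen receptor, had a log2 fold of 0.18 (0.13 to 0.24) and Pgr, the progesterone receptor, of -0.35 (-0.41 to -0.29). The median of the 17 steroid receptor and coregulator genes was 0.03, with Greb1, an estrogen receptor cofactor and target, at 2.68 and Fkbp4, a cochaperone of the progesterone receptor, at -0.82. Stromal progesterone and hedgehog response genes had a median of -0.01 over 22 genes, 17 of which differed by less than 1.5-fold or had few counts, and their mean was 0.10. Hand2, which restrains epithelial growth factors downstream of progesterone, had a log2 fold of -0.16 and Hoxa10 of -0.55. Cebpb (2.35) and Wnt4 (1.79) were higher, and Zbtb16 was lower (-0.97). Bmp2 had a log2 fold of 0.67 and Fgf2 of 0.84, or 1.46 and 0.01 in the shared cluster. Igf1, a growth factor that acts on the epithelium, stood at 2024 CPM in f/f and 1127 CPM in d/d (-0.84, -0.87 to -0.82). Growth factor and epithelial mitogen genes had a median of 0.89 over 11 genes, with 5 higher and 3 lower, -0.09 in the shared cluster and -0.47 when their UMIs were summed. Hgf stood at -1.31 and Igfbp3 at 0.89, the latter with 1.63 in the shared cluster and -2.30 in the other clusters. Decidualization genes had a median of 1.07 over 14 genes and 0.10 in the shared cluster, with 5 higher and 1 lower, and 0.29 when their UMIs were summed. Inhbb stood at 4.32, Hbegf at 3.22 and Cryab at 1.90, or 1.80, 3.69 and -0.02 in the shared cluster. Hbegf was at least 2-fold higher in every compared class. Lif had 45 UMIs in f/f and 76 in d/d stroma (log2 fold 2.13, and 0.32 in the shared cluster).

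Extracellular matrix genes had a median log2 fold of 0.52 in stroma, with 11 of 24 higher and 2 lower, but -0.45 in the shared cluster. Col1a1, a major fibrillar collagen, had a log2 fold of 1.18 over all stroma and -0.52 in the shared cluster, and Lox, a collagen crosslinking enzyme, 1.51 and -0.35. Eln stood at 1.49 and Bgn at 1.32. Matrix remodelling genes had a median of 0.84 and 0.32 in the shared cluster, with the gelatinase gene Mmp2 at 1.64. Wnt pathway genes had a median of 0.73 and 0.02 in the shared cluster. Lef1, a transcription factor of this pathway, stood at 68.4 CPM in f/f and 6.83 CPM in d/d (-3.32) and had a log2 fold of -3.63 in the shared cluster. Medians of ribosomal protein genes (-0.09), mitochondrially encoded genes (-0.06), glycolysis genes (-0.11, mean 0.24) and cholesterol synthesis genes (0.05, mean -0.03) lay within the central 95% of random lists. Oxidative phosphorylation genes had a median of -0.24 and unfolded protein response genes of -0.34, also within it. In the shared cluster these lay below it at -0.36 and -0.74, and ribosomal protein genes above it at 0.15.

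The stromal genes with the largest differences by counting interval included, on the higher side, Hes1, a Notch target (log2 fold 3.68), A2m (3.68), Itgbl1 (4.16), Egr3 (3.54), Gadd45g (3.34), Pim1 (3.27) and Hmox1, a heme-degrading stress enzyme (3.15). On the lower side were Tac2, a tachykinin precursor (-5.24), Vit (-4.37), Nt5e, which produces adenosine (-4.36), Rgs2, a regulator of G protein signalling (-3.64), the endothelin receptor Ednrb (-3.94), Nsg2 (-3.34), Ppfia2 (-3.29), Smoc1 (-3.02), Cyp1b1 (-3.20), Lamc3 (-3.07) and Col23a1 (-2.97). Rgs2 was abundant, at 1070 CPM in f/f and 86.0 CPM in d/d. Itgbl1, A2m, Cxcl14 and Mmp2 are among the 10 leading genes of cluster 4, and Vit, Lef1 and Cyp1b1 among those of f/f clusters 1 and 9, so their folds partly restate the cluster split. Within the shared cluster the log2 folds were 1.77 for Itgbl1, 1.42 for A2m, -2.75 for Vit, -0.79 for Cyp1b1, 2.36 for Cdkn1a, 1.45 for Hes1, 1.44 for Gadd45g, 1.94 for Pim1 and -3.21 for Rgs2, with 0.99 for Mmp2.

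**Figure D3:**
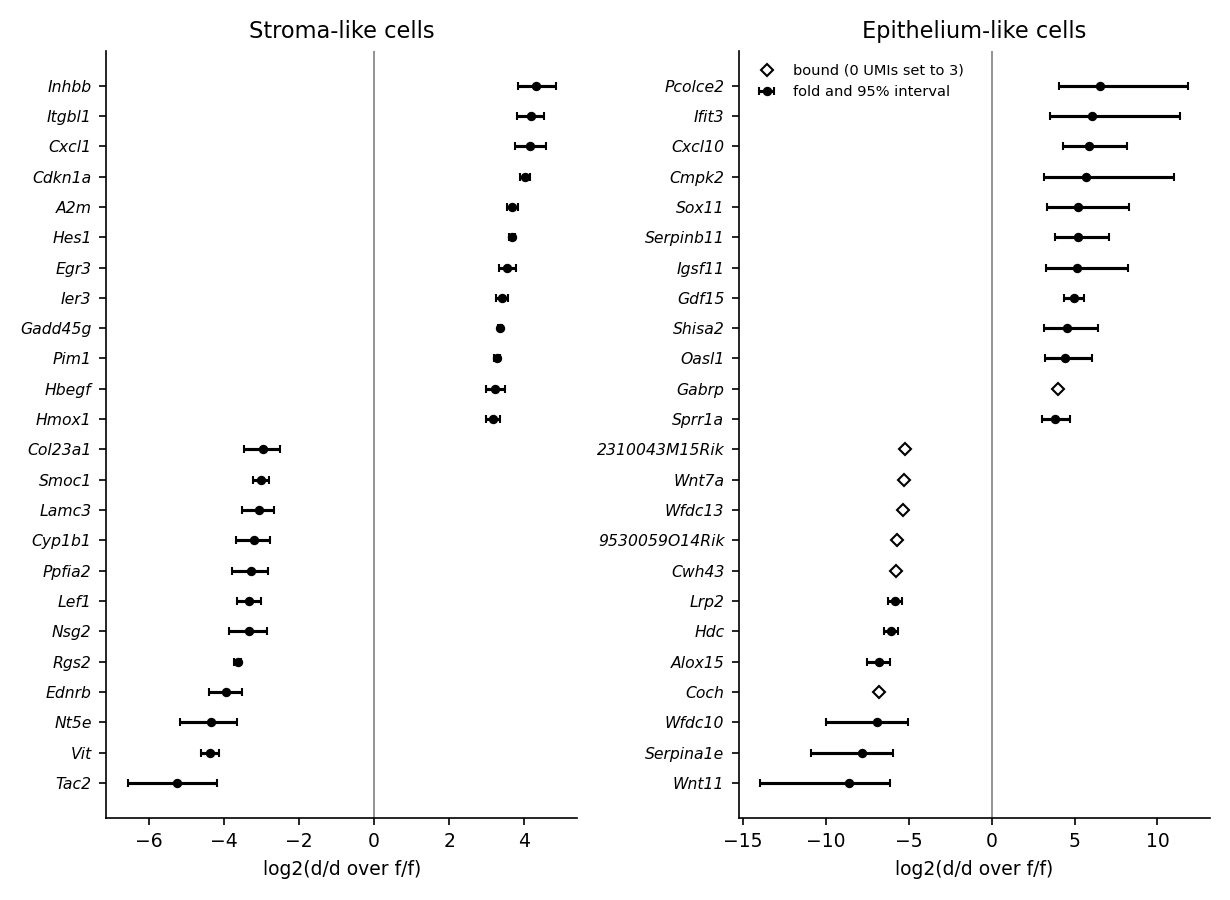
Log2 fold (d/d over f/f) of the 12 genes with the highest and the 12 with the lowest values by counting interval in stroma-like and epithelium-like cells, with 95% intervals for counting error. Open diamonds are bounds for genes with 0 UMIs in 1 library, set to 3 UMIs, such as Coch and Gabrp in the epithelium.

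Epithelium-like cells had lower levels of progesterone response genes and higher levels of proliferation and interferon genes in the d/d library. The progesterone response and receptivity genes had a median log2 fold of -2.24 (-2.72 to -1.82) over 20 measured genes, with 11 lower and 0 higher, below all random lists. It was -1.13 for genes with at least 100 UMIs and -1.08 when UMIs were summed. Proliferation genes had a median of 1.93 (1.34 to 2.27), with 13 of 23 higher and 0 lower, above all random lists. It was 1.18 against luminal-like cells, with 14 higher and 2 lower, also 1.18 when UMIs were summed, and 1.16 with the endothelial-led sub-cluster kept. Mki67 stood at 2.77 CPM in f/f (6 UMIs) and 39.0 CPM in d/d (178 UMIs), a log2 fold of 3.82 (2.67 to 5.28). Cdk1 (3.92), Ube2c (3.75) and Cenpf (13.9-fold) were also higher. The f/f epithelium fell into 73 luminal-like and 100 glandular-like cells. Of the 156 d/d cells 1 was luminal-like and 6 were glandular-like, and 149 lay in a sub-cluster, with 4 f/f cells, that matched neither part. Epithelium-like cells had a median of 9399 UMIs in f/f and 17742 in d/d, and that sub-cluster one of 18120. Cluster 18 held 41.2% of f/f epithelium and 0.641% of d/d epithelium, the rest of both lying in cluster 13. Another sub-cluster of 88 f/f and 5 d/d cells, led by endothelial genes, was left out. Because the parts differ, d/d cells were also set against each f/f part. Most genes of the gland list and several of the progesterone list were also markers used to name these parts.

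Against f/f luminal-like cells the progesterone median was -2.37 and against f/f glandular-like cells -0.13 (-0.45 to -0.07). Hdc, the histamine-synthesizing enzyme, stood at 662 CPM in f/f and 10.1 CPM in d/d (-6.04), and was also lower against glandular-like cells alone (-4.48). Lrp2, an endocytic receptor gene (-5.80), and Calb1, a calcium-binding protein gene (-4.62), were lower, with -0.80 and -0.02 against glandular-like cells. Wnt7a had 55 UMIs in f/f and 0 in d/d, at least 38.5-fold lower with 0 set to 3 UMIs, or a log2 fold of at most -4.92 by the exact interval. Ihh, the hedgehog ligand that signals to the stroma, had a log2 fold of 0.17 (-0.01 to 0.35). Areg had 0.53 (0.30 to 0.77), with -0.40 against luminal-like and 3.23 against glandular-like cells. Pgr had -0.42, with -0.87 against luminal-like and 0.19 against glandular-like cells. Esr1 had -0.29, with 1.48 against luminal-like and -1.02 against glandular-like cells.

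Estrogen response genes had a median log2 fold of 0.93 over 15 genes, with 8 higher and 3 lower (0.80 against luminal-like cells, and an interval of 0.63 to 1.22 against glandular-like cells). With UMIs summed the values were 0.01 over all, -0.34 against luminal-like and 0.41 against glandular-like cells. Ltf, the lactoferrin gene and a classic estrogen target, stood at 19.4 CPM in f/f and 49.8 CPM in d/d (1.36, 0.88 to 1.87), and Muc1, a cell surface mucin, at 63.6 and 97.8 CPM (0.62). Padi1 (2.11), the water channel gene Aqp5 (1.98) and Cdkn1a (3.01) were higher, and Fgfr2, a receptor for stromal growth factors, was lower (-1.80). Cdkn1a was at least 2-fold higher in every compared class, so its fold is not particular to this list or class. Gland secretory genes had a median of -0.40 over 11 genes, which was -1.08 (-1.19 to -0.99) against glandular-like and 2.46 against luminal-like cells. With UMIs summed the values were -1.78, -2.06 and -1.41, so the sign against luminal-like cells changed. Spink1 (-3.99), Ttr (-4.41), Ovgp1 (-4.74) and Fxyd4 (-3.24) were lower, with -4.90, -5.36, -3.89 and 0.69 against glandular-like cells and -0.03, 2.46, -5.29 and -4.24 against luminal-like cells. Lif, the gland cytokine needed for implantation, stood at 82.5 CPM in f/f and 29.4 CPM in d/d (-1.49, -1.82 to -1.16). Its log2 fold was -2.44 against f/f glandular-like cells and 3.94 against luminal-like cells.

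Interferon response genes had a median log2 fold of 0.97 in the epithelium, with 17 of 27 higher and 1 lower. It was 2.14 against glandular-like cells, with 21 higher, and 0.68 against luminal-like cells, with 12 higher and 2 lower, where summed UMIs gave 0.32. Cxcl10, an interferon-induced chemokine, had 3 UMIs in f/f and 368 in d/d (5.87, 4.31 to 8.15), and was at least 2-fold higher in every compared class. Ifit3 had 1 and 138 (6.04, 3.53 to 11.35), and Rsad2 had 2 and 115 (4.77). Antigen presentation genes had a median of 0.67, with H2-D1 at 1.26 and H2-K1 at 1.07. Immediate early and heat shock genes had a median of 0.28, with 4 of 18 higher and 2 lower (0.15 against glandular-like cells), against 1.01 to 2.11 in the other compared classes. Hspa1a stood at 2.35 and Dusp1 at -2.09. Ribosomal protein genes had a median of 0.42 and extracellular matrix genes of -1.35. Stromal markers in epithelium stood at 4.32% of their level in stroma in f/f and 1.08% in d/d (643 and 276 CPM). That level in stroma itself was 14873 CPM in f/f and 25571 CPM in d/d, which lowers all such percentages in d/d. Cell junction genes had a median of -0.13 and, with UMIs summed, 0.11, with Cldn4 at 2.04.

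Other epithelial genes with large differences were Gdf15, a stress-induced cytokine (26 UMIs in f/f and 1683 in d/d, log2 fold 4.94), Serpinb11 (5.20), Oasl1 (4.45), Shisa2 (4.54) and Sprr1a (3.83). Pcolce2 had 1 UMI in f/f and 197 in d/d (6.55, 4.06 to 11.86), Sox11 2 and 158 (5.23, 3.35 to 8.29), Igsf11 2 and 150 (5.16) and Cmpk2 1 and 108 (5.68). Gabrp, a GABA receptor subunit gene, had 0 and 100 UMIs, at least 15.9-fold higher with 0 set to 3 UMIs, or a log2 fold of at least 3.66 by the exact interval. On the lower side Coch had 158 UMIs in f/f and 0 in d/d, at least 111-fold lower, Cwh43 at least 54.7-fold and Wfdc13 at least 40.6-fold. Alox15, a lipoxygenase, stood at 456 and 4.17 CPM (-6.77), and was at -5.43 against glandular-like cells. Wnt11 had 187 and 1 UMIs (-8.62, -13.93 to -6.12), Serpina1e 215 and 2 (-7.82) and Wfdc10 116 and 2 (-6.93). Gdf15, Serpinb11, Sox11, Shisa2, Pcolce2, Igsf11 and Oasl1 lead the d/d sub-cluster, Lrp2, Calb1, Coch, Wnt11 and Serpina1e lead the luminal-like one, Ttr and Spink1 the glandular-like one, and Hdc, Alox15 and Fxyd4 lead cluster 18. These folds therefore describe the same split of cells.

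Smooth muscle-like cells, which lay in clusters 2 and 7 in both libraries, had higher immediate early genes and lower matrix genes in the d/d library. Immediate early and heat shock genes had a median log2 fold of 1.01 (0.94 to 1.08), with 13 of 18 higher and 0 lower, among them Nr4a1 (2.00) and Egr1 (1.72). Inflammatory mediators had a median of 1.04 and p53 response genes of 0.61. Extracellular matrix genes had a median of -0.57 (-0.65 to -0.47), with 11 of 24 lower and 1 higher. Fn1, the fibronectin gene, stood at 1156 CPM in f/f and 216 CPM in d/d (-2.42), Col12a1 at -1.81, Col6a3 at -1.60 and Postn at -1.49. Stromal markers in these cells stood at 29.7% of their level in stroma in f/f and 13.2% in d/d (4420 and 3363 CPM). Contraction genes had a median of -0.29, within the central 95% of random lists, with 6 of 17 lower and 0 higher, among them Des (-1.36), Smtn (-1.33) and Actg2 (-0.89). Among the largest differences were Gadd45b (3.33), Hmox1 (3.47), Nfkbia (2.76), Egr3 (2.70), Mir17hg (3.62), Fabp3 (2.79), Dbp, a circadian transcription factor (2.59), Hbegf (2.53), Sertad1 (2.34), Tnfrsf12a (2.45) and AY036118 (2.71). Unc13c had 3 and 201 UMIs (3.91, 2.34 to 6.20). Lower were Col15a1 (-3.52), Atp12a (-3.22), Hsd11b2, which inactivates glucocorticoids (-2.49), Spon2 (-2.48) and Wisp1 (-2.13). Hsd11b2 is a leading gene of the f/f stromal cluster 0, so free stromal RNA could supply it in f/f. Haemoglobin transcripts, which belong to red blood cells, were lower too, with Hbb-bs at 228 CPM in f/f and 3.90 CPM in d/d (-5.87), Hba-a1 at -6.38, Hba-a2 at -7.69 and Hbb-bt, which had 235 and 3 UMIs, at -8.45 (-10.74 to -6.88). Esr1 had a log2 fold of -0.32 and Pgr of -0.07.

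Pericyte-like cells had lower proliferation genes in the d/d library. Their median log2 fold was -2.45 (-2.65 to -2.21), with 22 of 24 lower and 0 higher. In cluster 6, which held 67.1% of f/f and 50.1% of d/d pericytes, it was -1.09, but only 1 of 18 genes was lower and 1 higher, and summed UMIs gave -0.28. Cluster 21, led by mitotic genes, held 58 f/f and 12 d/d cells, and cluster 8, with no pericyte marker among its 10 leading genes, held 17.5% and 48.9% of pericytes. Folds over all pericytes therefore also carry this difference in makeup. Top2a stood at -2.91 and Mki67 at -2.86. Immediate early genes had a median of 1.61 and unfolded protein response genes of -0.83. Cdkn1a stood at 15.8 CPM in f/f and 485 CPM in d/d (4.95), Gdf15 at 4.14 and the metallothionein gene Mt1 at 3.65. Has1, a hyaluronan synthase, had 1 and 531 UMIs (7.70, 5.21 to 13.01). The imprinted genes Mest (-5.19) and H19 (-4.70) and the growth factor gene Igf1 (-3.11) were lower, and Bmp2 was higher (1.54). Stromal markers in pericytes stood at 61.9% of their level in stroma in f/f and 28.9% in d/d (9208 and 7392 CPM).

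Blood endothelium-like cells, in which Mettl14 was close in both libraries, also had higher immediate early and lower proliferation genes in d/d. The immediate early and heat shock median was 1.48 (1.45 to 1.54), and 1.14 in cluster 5, which held 98.8% of f/f and 62.1% of d/d endothelium. Clusters 16 and 20 held 22.7% and 15.2% of d/d endothelium, and 1.02% and 0.204% of f/f endothelium. Selp, Sele and Vwf were among the leading genes of cluster 16, and Sema3g, Dll4 and Gja5 among those of cluster 20. The proliferation median was -0.77 (-0.90 to -0.67), with 15 of 24 lower and 1 higher, among them Top2a (-1.53) and Cenpf (-1.60), and -0.32 in cluster 5. Hmox1 stood at 27.4 CPM in f/f and 781 CPM in d/d (4.83), Cdkn1a at 2.90, Hlf at 3.17 and AY036118 at 2.73. Hist1h2ap, a histone gene, stood at -3.95, Car4 at -3.73 and Lgals1 at -2.54. Angiogenesis genes had a median of 0.46, with Flt1, a VEGF receptor, at 0.99, Sox17 at 1.08 and Aplnr at -0.94. Aplnr is a leading gene of cluster 5, and Dll4, also in this list, one of cluster 20. Folds of this list may therefore partly restate the cluster split. Interferon response genes had a median of 0.51 and extracellular matrix genes of -0.78, with stromal markers at 9.05% of their stromal level in f/f and 2.81% in d/d (1346 and 718 CPM).

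Macrophage- or monocyte-like cells had higher levels of inflammatory genes in the d/d library. Of 15 inflammatory mediators 10 were higher and 2 lower, with a median log2 fold of 3.04 (2.80 to 3.24). Cxcl2, a neutrophil attractant, stood at 433 CPM in f/f and 9673 CPM in d/d (4.48), and Ptgs2, a prostaglandin synthase, at 25.4 and 701 CPM (4.78). Cxcl1 had 1 and 347 UMIs (7.36, 4.87 to 12.67), and Il1a had 0 and 155, at least 24.5-fold higher with 0 set to 3 UMIs. This bound leaves out counting error in d/d. Interferon response genes had a median of 0.57 and antigen presentation genes of 0.61, with Cxcl9 at 3.51, Isg15 at 3.38 and H2-D1 at 1.05. Ccl8 was lower (-3.05) and is a leading gene of cluster 23, which held 22.4% of f/f and 0% of d/d macrophages, while cluster 10 held the rest of both. Stromal markers stood at 39.7% of their stromal level in f/f macrophages and 3.29% in d/d (5909 and 842 CPM), and the lowest genes were stromal transcripts such as Maob (-4.91), Fst (72 and 2 UMIs, -6.25, -9.32 to -4.34), Vit (63 and 2 UMIs, -6.06, -9.13 to -4.14) and Angptl7 (81 and 1 UMIs, -7.42, -12.74 to -4.90).

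**Figure D4:**
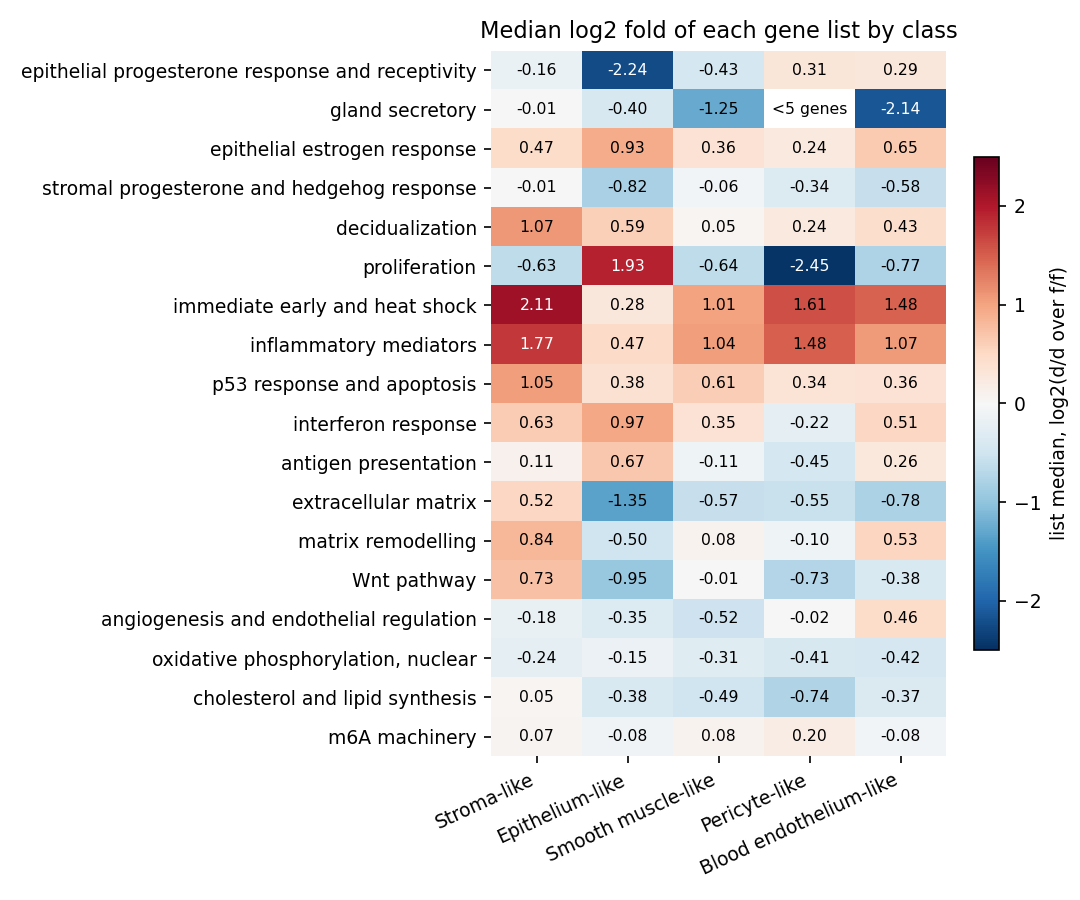
Median log2 fold (d/d over f/f) of 18 gene lists, in rows, in 5 cell classes, in columns, on a colour scale from -2.5 to 2.5. Proliferation genes stand at 1.93 in epithelium-like and -2.45 in pericyte-like cells, and immediate early and heat shock genes at 0.28 in epithelium-like and 2.11 in stroma-like cells.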

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

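Of the tests below, only that of a mixture of luminal-like and glandular-like cells was set before its result was seen, and all others were chosen afterwards. Gene groups that moved in opposite directions between cell classes were noted, and these differences were not themselves tested. Proliferation genes had a median log2 fold of 1.93 in epithelium-like and -2.45 in pericyte-like cells, a difference of 4.38. Both values were smaller elsewhere, with 1.18 in epithelium and -1.61 in pericytes when UMIs were summed, 1.18 against f/f luminal-like cells, and -1.09 in the shared pericyte cluster, where 1 of 18 genes was lower and 1 higher. Fibroblast growth factor and epithelial mitogen genes had a median of 0.89 in stroma-like and -1.29 in epithelium-like cells, a difference of 2.17. Neither value was stable, with -0.09 in the shared stromal cluster, 0.13 in the other stromal clusters and -0.47 with UMIs summed, and in epithelium -0.59 with UMIs summed and also -0.59 against f/f glandular-like cells, within the central 95% of random lists. Stromal markers in epithelium also stood at 4.32% of their stromal level in f/f and 1.08% in d/d (643 and 276 CPM).

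The median log2 fold of immediate early and heat shock genes was above 0 in each of the 6 compared classes, although in epithelium only 4 of 18 genes were higher and 2 were lower. In the shared cluster of blood endothelium the Mettl14 ratio was 1.03 (0.735 to 1.44) and the list median was still 1.14 (1.09 to 1.18). A fall of Mettl14 RNA in the same cells was therefore not needed for higher values there. This does not test the classes in which Mettl14 RNA was lower, such as stroma, and equal tag levels do not show intact transcripts. Longer or harsher handling of the d/d tissue would raise these genes in every class, and the lowest class median, in epithelium, was 0.28 (0.24 to 0.34). Against f/f glandular-like cells it was 0.15, at percentile 89.6 of random lists. With 1 sample per genotype, handling and genotype cannot be told apart for these genes. An indirect effect of the genotype on endothelium through other cells stays open and untested.

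In d/d epithelium progesterone response genes were lower and proliferation genes higher. A loss of luminal cells alone does not account for the proliferation genes, since the lower of their medians against f/f luminal-like and glandular-like cells was 1.18 (0.91 to 1.78). No mixture of both f/f parts matched progesterone and gland genes together. The best one, with 2% luminal cells, left median residuals of -0.89 for progesterone and -1.06 for gland genes. The larger had a size of 1.06 (0.96 to 1.15). Most gland genes and several progesterone genes were also markers that named these parts, so these residuals are not independent of the naming. For the progesterone genes alone the median against f/f glandular-like cells was -0.13 (-0.45 to -0.07). It was -0.42 for the genes used in the mixture, with no luminal cells in it. A loss of luminal cells is thus a candidate explanation, but these values cannot tell it from lower expression in luminal cells. Several progesterone genes named the luminal-like part, so luminal cells that lost them might not be called luminal-like. Single genes varied widely against glandular-like cells, with Hdc at -4.48 and Areg at 3.23. A shift of cycling genes in the whole d/d library was argued against by stroma, where the proliferation median was -0.63 (-0.70 to -0.51).

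The share of stroma was lower and that of smooth muscle higher in d/d. If only stromal cells were missing, all other shares would be raised alike, but the ratio of smooth muscle was 3.76 times that of epithelium. A different release of cell types from the tissue stays open, since with 1 sample per genotype the smooth muscle ratio of 3.93 (3.54 to 4.38) cannot be told apart from a difference in dissociation. A difference in tissue composition between the genotypes was not tested.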

How the results depend on the processing

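The comparisons within shared clusters, against single f/f epithelial parts and with the endothelial-led sub-cluster kept were chosen after the results were seen. No paired analysis was possible because there was 1 library per genotype and no test. Over all settings the Mettl14 ratio ranged from 0.339 to 0.363 over all cells and from 0.160 to 0.189 in stroma, and the stroma share ratio from 0.416 to 0.458. Of 2349 list medians under the first set of alternatives 1878 stayed within their counting intervals, 460 moved with the same sign or were not called and 11 changed sign. Of 1991 values of the gene folds named in the text 194 moved there, and none whose interval excluded 0 changed sign. The causes were not tested. Clustering each library separately gave a smooth muscle ratio of 5.13, 0.0% glandular-like cells in d/d epithelium and a stromal proliferation median of -0.50. Without a mitochondrial filter the smooth muscle ratio was 4.59 and the pericyte ratio 2.76, and with a limit of 10% the glandular-like share was 1.40%. TMM scaling gave 2.16 for stromal immediate early genes and 0.085 for macrophage ribosomal protein genes (-0.39 without it). With equal weight per cell stromal proliferation was -0.79 and epithelial progesterone response -1.71. With at least 100 UMIs per gene epithelial progesterone response was -1.13. Macrophage decidualization genes, with a main median below 0, were at 4.17 with at least 100 UMIs per gene and at 0.24 with no minimum. The value of 4.17 is the fold of Hbegf, which was higher in every compared class. With no minimum epithelial decidual immune genes were at -0.072. The list mean gave 1.92 for stromal immediate early genes. Summed UMIs gave 1.64 for these, -0.34 for stromal and 1.18 for epithelial proliferation, -1.08 for epithelial progesterone response, -0.47 for stromal growth factors, 1.53 for macrophage decidualization, and 0.20 in epithelium and 0.056 in endothelium for stromal progesterone genes. Pericyte decidual immune genes were at -0.14 with doublets kept and -0.10 with the automatic threshold, which put pericyte ribosomal protein genes at -0.022.

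In the shared stromal cluster proliferation was at -1.10, immediate early genes at 1.07, growth factors at -0.0945 and matrix genes at -0.45, with Cryab at -0.022, Lox at -0.35, Cxcl14 at -0.43 and Col1a1 at -0.52. In the other stromal clusters the values were -0.42 for proliferation, 2.02 for immediate early and -0.16 for decidual immune genes, -2.30 for Igfbp3 and 0.063 for Hand2. Against f/f glandular-like cells progesterone response was at -0.13, Pgr at 0.19 and Fxyd4 at 0.69. Against luminal-like cells proliferation was at 1.18, Areg at -0.40, Esr1 at 1.48, Ttr at 2.46 and Lif at 3.94. With the endothelial-led sub-cluster kept, epithelial proliferation was at 1.16 and contraction genes at -0.81.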

Other observations

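The gene set below was chosen after the results were seen. Of 3014 genes measured in all 6 compared classes, 18 were at least 2-fold higher and 3 at least 2-fold lower in the d/d library in every class. The higher genes included Cdkn1a, with log2 folds from 1.61 in smooth muscle to 4.95 in pericytes, Gadd45b (2.04 to 4.21), Tnfrsf12a (2.27 to 4.12), Hmox1 (1.71 to 4.83) and Isg15 (1.25 to 3.38). Hbegf (1.74 to 4.17) and Cxcl10 (1.35 to 5.87) were among the higher genes too. The lower ones were Gm10076, Maob and Vit, and Vit and Maob lead the f/f stromal cluster 1. The free RNA limit used for the named genes was not applied to this set. Free stromal RNA could therefore supply Vit and Maob in the other f/f classes, and their folds there need not describe those cells. B or plasma cell-like cells numbered 1 in f/f and 27 in d/d, a share ratio of 32.1 (5.28 to 1312). Dendritic cell-like cells made up 0.902% and 0.736% of kept cells, and lymphatic endothelium-like cells 1.14% and 1.02%. Neither direction held, with a dendritic ratio of 0.816 that was 2.58 (libraries clustered separately) and a lymphatic ratio of 0.894 that was 2.07 (minimum of 2000 UMIs). The unnamed cluster 15, with 109 f/f and 108 d/d cells, had the dendritic markers Cd209a and Ccr7 among its leading genes. The dendritic shares may therefore leave out part of these cells.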
